A study of Mus musculus with 24 samples.

How the data were processed

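The libraries came from mouse lung organoids, which are small epithelial structures grown from primary lung epithelial cells mixed with CCL206 cells, a mouse lung fibroblast line, in a gel of basement membrane proteins. Per the labels' protocols, the cultures received 5% cigarette smoke extract or vehicle for the first 14 days. They were then taken apart, the same number of epithelial cells was plated again with CCL206 fibroblasts that had not been in the first culture, and vehicle or a drug pair was given until day 28. The pair was 100 nM tanimilast, an inhibitor of phosphodiesterase 4 (PDE4, the enzyme family that breaks down cyclic AMP), and 100 nM formoterol, a bronchodilator. Libraries were made from cells with the surface protein Epcam, called the epithelial fraction here, and from cells without it, called the fibroblast fraction here. How the cells were separated is not given in the sources used here. The 4 treatments, 2 fractions and 3 mice gave 24 libraries in 8 groups of 3. The labels give a mouse number as the batch, which is read here as the animal that gave the epithelial cells, since the fibroblasts were a cell line. P-values therefore measured the spread between 3 animals and their cultures, and for the fibroblasts the spread between cultures of a single line.

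The values used were deposited counts of reads per gene, as whole numbers that had not been normalised. Per the labels' protocols, RNA with poly-A tails was sequenced, and per the submitters' processing notes reads were trimmed with Trimmomatic 0.30 and DESeq2 was named for the authors' own tests, which are not used here. The aligner and the counter are not given in the sources used here. Whether counting used strand is not given either. Overlapping, antisense and near-identical genes, such as the secretoglobins and serpins, can therefore share reads. Per the labels' protocols the reference was called GRCh38.p14 and mouse in the same place, and that name belongs to a human assembly. The mouse build is therefore not settled, and no coordinate is printed. The count table had 49280 features, of which 43339 carried Ensembl mouse identifiers with symbols and 5941 were loci named NewGene with no symbol. NewGene loci held 0.574 to 1.07% of the counts of a library and stayed in the tests. Older symbols were matched through a RefSeq table of assembly GRCm38.p6, used for names only, and 550 of 551 members of the gene lists were found. Each library had between 31832267 and 47534709 counts. Levels are given as CPM, counts scaled by library size, of which 1 stood for at least 31.8 counts. Mitochondrial genes took 3.94 to 6.77% of the counts. Intervals and tests cover the spread between animals and counting error and no bias of the library preparation. Among the 24 pairs of replicates compared, 0 held identical values, and the chi-square of their counts per degree of freedom was between 14.1 and 119, so no library was counted as a copy of another.

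Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, its filter on low counts by group, and robust quasi-likelihood F tests. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 is called. Each fraction was fitted as 4 group means over its 12 libraries, with no mouse term. The contrasts were smoke extract against vehicle without drugs, drugs against vehicle without and after smoke extract, both effects averaged over the other factor, and their interaction. The fractions were compared over all 24 libraries, as was the difference of the drug effect between them. Effects are given as log2 fold changes with their standard errors (SE), and levels as mean CPM with SD and n. After these tests, 37 gene lists for lung cell types, other cell types and pathways were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, where at least 4 members were tested. They were adjusted over the lists within a comparison. Camera was repeated with an estimated correlation, and fry, which asks whether a list's genes move and compares them with no other genes, was added after the data were seen. Called members were also counted after adjustment over the list alone. The groups, contrasts, main test, gene lists, the rule for named genes and most alternative settings were chosen before the data were examined. Wnt2, a gene of the fixed set, did not pass the filter on low counts in any fit.

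The genes named are, per comparison, the 8 with the largest rise and the 8 with the largest fall among called genes, with at least 5 CPM in the higher arm and the same direction in each mouse pair, leaving out predicted genes. Added to these are the 3 members with the smallest p of each list that passed camera, a fixed set that includes PDE4 genes and cell markers, and the 5 genes with the smallest p where under 5 were called. The rule was applied to the fits with and without the mouse term. A gene named outside the rule is said to be so.

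Mouse numbers pair the libraries, since the same number marks the same animal. Deviations from the group means of libraries of the same mouse correlated across genes with a mean r of 0.38 in the epithelial fraction, between -0.03 and 0.72 over 18 pairs, and 0.28 in the fibroblast fraction, between 0.01 and 0.68. For different mice the mean r was -0.19 and -0.14 over 36 pairs each. Deviations from a group mean cancel within the group, so a positive same-mouse mean forces a negative mean between different mice. The values for different mice are therefore no separate evidence of pairing. Genes are not independent replicates in these correlations. The fit with mouse as a block was therefore run beside each result. Alternatives were other size factors, no filter, DESeq2 1.42.0, the mouse block, a covariate for the share of cells of the other fraction, only the compared groups, and leaving out each replicate or library.

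The scripts were tested on simulated counts drawn from the means, spread and library sizes of these libraries, with 100 genes changed 2-fold and 100 changed 4-fold. For the averaged drug effect over 18038 genes in the epithelial fraction, 95% of the 2-fold and 96% of the 4-fold changes were recovered without the block, with 3 unchanged genes called. With the block, 98% of each size was recovered and 17 unchanged genes were called. In the fibroblast fraction, over 18287 genes, 90% and 97% were recovered without the block with 1 unchanged gene called, and 96% and 97% with the block with 6 unchanged genes called. For the drug effect without smoke extract in the fibroblast fraction, 78% and 91% were recovered without the block. For the comparison of fractions over 19142 genes, 94% of the 2-fold and 100% of the 4-fold changes were recovered. Camera called the changed list and 0 other lists in each fraction's averaged drug effect. The counts of each gene were drawn on their own, so this does not show how often camera calls lists whose genes vary together.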

Results

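The data were 24 RNA libraries of mouse lung organoids, made of primary lung epithelial cells and CCL206 fibroblasts. Cultures had 5% cigarette smoke extract (CSE) or vehicle for 14 days, and then, with fresh fibroblasts, vehicle or tanimilast with formoterol until day 28. Groups are written Veh, CSE, TF (drugs only) and CSETF (CSE, then drugs), after Epi for the Epcam-positive and Fib for the Epcam-negative fraction, with 3 mice each. A positive log2 fold change is higher with drugs, after CSE, or in the epithelial fraction.

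Epithelial and fibroblast genes parted the fractions, while the fibroblast fraction kept much epithelial RNA. Epcam, the surface protein that defines the fractions, averaged 1254 CPM (SD 293, n = 12) in the epithelial libraries and 443 (SD 134, n = 12) in the fibroblast libraries. Its log2 fold change was 1.52 ± 0.14 (SE; adjusted p = 1.08e-08). Rises in the epithelial fraction also included the keratins Krt8 (1.34 ± 0.10), Krt5 (1.63 ± 0.19), which marks basal cells, and Krt17 (1.96 ± 0.23), along with the tight junction genes Cldn1 (2.29 ± 0.21) and Cldn6 (2.10 ± 0.23). Others were the kinase gene Nrk (2.59 ± 0.34), the cornified envelope gene Crct1 (2.38 ± 0.23), the protease gene Tmprss11e (2.36 ± 0.30), the G protein regulator Rgs16 (2.11 ± 0.18) and the platelet chemokine gene Ppbp (2.09 ± 0.39). The collagens Col1a1, Col3a1 (both -3.14, SE 0.33 and 0.36) and Col5a3 (-3.96 ± 0.59) were lower in it. So were Adamts2, which trims procollagen (-3.43 ± 0.55), the protease inhibitor Serpina3h (-3.76 ± 0.56), the amino acid transporter Slc38a4 (-3.49 ± 0.62), the homeobox gene Rhox5 (-3.38 ± 0.57) and Igfbp6, which binds insulin-like growth factors (-3.14 ± 0.29). Among these falls and the rises before them, Ppbp had the largest adjusted p, 8.71e-05. The growth factors Fgf7 (-2.47 ± 0.19), Fgf10 (-2.52 ± 0.24) and Hgf (-2.65 ± 0.28), the cytokine Il6 (-2.84 ± 0.27), the heme oxygenase gene Hmox1 (-1.64 ± 0.09) and smooth muscle actin, Acta2 (-2.62 ± 0.56), were also lower. In all, 13180 of 19142 genes passed, 6636 up and 6544 down.

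Scgb1a1 and Sftpc did not differ between the fractions at the threshold. The club cell gene Scgb1a1 averaged 130 CPM (SD 144, n = 12) in the epithelial and 159 (SD 229, n = 12) in the fibroblast libraries, with a log2 fold change of 0.35 ± 0.40 (adjusted p = 0.458). The fold is a mean over groups on the log scale and was up in 8 of 12 pairs. The mean CPM was drawn up by the groups with CSE in both fractions. Their libraries held 97.5 to 576 CPM in FibCSE, 124 to 676 in FibCSETF, 110 to 454 in EpiCSE and 127 to 365 in EpiCSETF. Without CSE the highest library held 88 CPM, in EpiVeh. Surfactant protein C, Sftpc, had -0.44 ± 0.38 (adjusted p = 0.31), and the alveolar type 1 gene Ager -0.45 ± 0.23 (adjusted p = 0.0867, and 0.0412 with mouse as a block). Among the PDE4 genes Pde4b was 0.79 ± 0.14 higher (adjusted p = 7.85e-05) and Pde4a lower, at -0.44 ± 0.11 (adjusted p = 0.00165, higher in 1 of 12 mouse pairs), while Pde4d was at -0.02 ± 0.06 (adjusted p = 0.843). The xenobiotic enzyme gene Cyp1b1 (0.76 ± 0.09) and Foxj1, a regulator of ciliated cells (0.96 ± 0.21, adjusted p = 0.000589), were higher. Cyp1a1 was lower (-1.26 ± 0.50, adjusted p = 0.0303), higher in 3 of 12 pairs, with means under 1 CPM. Not passing were Nqo1, a quinone reductase gene (0.20 ± 0.12), the chemokine gene Cxcl1 (adjusted p = 0.46) and Mki67, a gene of dividing cells (0.46 ± 0.21, adjusted p = 0.0617, and 7.86e-05 with the block).

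By list, 16 of 17 epithelial identity genes were higher in the epithelial fraction and 0 lower, among them Sox2 (1.11 ± 0.07), Esrp1 (1.19 ± 0.08) and Krt18 (1.30 ± 0.09; camera adjusted p = 3.36e-06). All 10 basal cell genes were higher, with Trp63 at 1.33 ± 0.11, Ngfr at 1.28 ± 0.11 and Krt6a at 1.79 ± 0.20 (adjusted p = 0.000612). Transitional cell genes were 13 up and 1 down of 15 (adjusted p = 0.00021). Goblet cell genes were 10 up of 11 with Muc16 at 1.34 ± 0.14 (adjusted p = 0.0249), and interferon genes 14 up and 2 down of 18 with Ifih1 at 0.90 ± 0.06 (adjusted p = 0.0133). The cholesterol synthesis genes were 16 up and 1 down of 18 (adjusted p = 0.00133). Fibroblast matrix genes were 18 down and 1 up of 20, with Fbln2 at -1.64 ± 0.10, Dcn at -2.60 ± 0.20 and Tnc at 1.66 ± 0.11 (adjusted p = 5.03e-06). Fibroblast identity genes were 8 down and 1 up of 10, with Prrx1 at -2.51 ± 0.17 and Pdgfrb at -2.88 ± 0.23 (adjusted p = 0.00284). With an estimated correlation 0 of these 8 lists passed, at adjusted p = 0.581 for the epithelial identity, basal, transitional, goblet and matrix lists, 0.631 for fibroblast identity, 0.67 for interferon and 0.739 for cholesterol. Adjusted over the list alone, epithelial identity kept 16 members up. Camera with an estimated correlation did not pass even this list, so a list that fails it is not shown to be unchanged. With the block 4 more lists passed, and with the block and an estimated correlation 0 lists did. They were support factors with Rspo3 at -2.31 ± 0.22 (0.0488, against 0.0539 without) and the unfolded protein response with Ddit3 at -1.38 ± 0.07 (0.025, against 0.0535). The others were club cells (0.0349, against 0.0979) and the cell cycle (0.0155, against 0.0922).

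**Figure D1:**
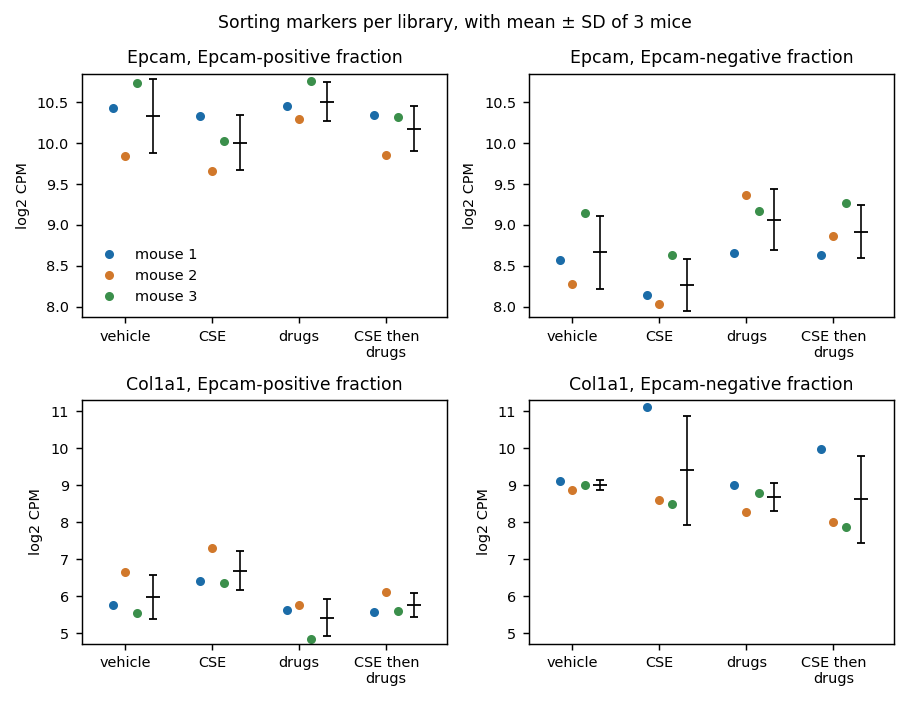
Log2 CPM of Epcam and Col1a1 in each library of the epithelial and fibroblast fractions. Points are libraries coloured by mouse, and bars show the mean and SD.

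In the epithelial fraction a single gene passed for the drugs, Pyy, which encodes the gut hormone peptide YY. Other splits of the libraries called as many genes in 5 of 100 cases, the real one included. A count of 1 in this fit, without a mouse term, was therefore not set apart from labels exchanged across mice. Averaged over CSE, Pyy rose by 2.16 ± 0.19 (adjusted p = 0.00342, up in 6 of 6 mouse pairs) at a low level, from 1.21 CPM (SD 0.155, n = 3) in EpiVeh to 5.84 (SD 0.506, n = 3) in EpiTF, and from 1.92 (SD 0.690, n = 3) in EpiCSE to 7.93 (SD 1.91, n = 3) in EpiCSETF. The values of the next genes were 1.12 ± 0.14 for the drug-metabolising enzyme gene Cyp2b10 (adjusted p = 0.0602), 0.76 ± 0.11 for Nr4a2, a nuclear receptor gene induced by cyclic AMP (adjusted p = 0.147), 0.47 ± 0.07 for the growth factor gene Areg (adjusted p = 0.147) and 0.35 ± 0.06 for the receptor gene Tgfbr1 (adjusted p = 0.205). DESeq2 called 69 genes, and 1138 of 18038 had an unadjusted p under 0.05. The count was 4 without EpiCSE replicate 1, 2 without EpiCSE replicate 2 or EpiCSETF replicate 3, and 0 without mouse 1 or mouse 3. For Pyy, epithelial drug effect averaged over CSE, the adjusted p was 0.673 without mouse 1, 0.247 without mouse 2 and 0.0638 without mouse 3.

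With mouse as a block 37 genes passed for the averaged drug effect, 28 up and 9 down. Labels exchanged within mice called as many in 1 of 32 cases, the real one included, with 0 as the highest other. The mucins Muc5b (1.94 ± 0.20, adjusted p = 0.0217) and Muc5ac (1.16 ± 0.12, adjusted p = 0.00961) rose in the fit with the block. So did Cyp2b10 (1.12 ± 0.12, adjusted p = 0.00961), the annexin gene Anxa10 (1.00 ± 0.13, adjusted p = 0.0263), the protease gene Ctse (0.81 ± 0.08, adjusted p = 0.00961), Nr4a2 (adjusted p = 0.0307) and the immune receptor gene Tigit (0.65 ± 0.08, adjusted p = 0.0168). Falls were those of Acta2 (-1.12 ± 0.15, adjusted p = 0.0248), Col3a1 (-0.72 ± 0.11, adjusted p = 0.0436), the Wnt antagonist gene Sfrp1 (-0.66 ± 0.11, adjusted p = 0.0449), Nrep, a neuronal regeneration gene (-0.56 ± 0.09, adjusted p = 0.0427), the clock gene Arntl (-0.55 ± 0.08, adjusted p = 0.0263) and the actin-binding gene Fam101b (-0.46 ± 0.06, adjusted p = 0.0217). Acta2 and Col3a1 are genes of the other fraction.

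Taken without CSE, the drug effect passed for 0 genes in edgeR, with 473 at an unadjusted p under 0.05, 9 in DESeq2, and Pyy with the block (2.30 ± 0.22, adjusted p = 0.0123). The smallest p without the block belonged to Pyy (2.28 ± 0.27, adjusted p = 0.0722), Areg (0.47 ± 0.10) and Nr4a2 (0.69 ± 0.16), both with an adjusted p of 1. After CSE it was also 0, with 754 at an unadjusted p under 0.05 and 15 in DESeq2, and Pyy passed with the block (2.06 ± 0.21, adjusted p = 0.025). There Pyy had 2.05 ± 0.26 and Cyp2b10 1.46 ± 0.20, both at an adjusted p of 0.136, and Nr4a2 0.82 ± 0.16 (adjusted p = 0.902). Leaving out EpiCSE replicate 3, EpiCSETF replicate 3 or mouse 3 gave 1 gene each.

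Of the lists, 10 of 36 passed camera for the averaged drug effect in the epithelial fraction, with 0 of their members called. Targets of cyclic AMP and CREB, its transcription factor, had a median of 0.10 over 22 genes, with 8 up when adjusted over the list alone (adjusted p = 8.19e-06, and adjusted p = 0.539 with an estimated correlation). Goblet cell genes had 0.32 over 11, with 2 up over the list alone (adjusted p = 0.00995, and adjusted p = 0.539 with an estimated correlation). The other lists with positive medians were transitional cells (0.09, adjusted p = 0.000846), ciliated cells with Tmem212 at 1.14 ± 0.24 (0.26, adjusted p = 0.0424), epithelial identity (0.16, adjusted p = 0.00297), NRF2 targets (0.06, adjusted p = 0.0424), interferon (0.12, adjusted p = 0.0292) and cholesterol (0.11, adjusted p = 0.0431). Fibroblast matrix with Col1a1 at -0.78 ± 0.25 (-0.63, adjusted p = 0.000118) and fibroblast identity with S100a4 at -0.92 ± 0.31 (-0.59, adjusted p = 0.00739) had negative medians. None of these passed with an estimated correlation, at adjusted p = 0.539 with an estimated correlation for 8 of the 10 lists, 0.794 for ciliated cells and 0.857 for cholesterol. For the drug effect without and after CSE 9 and 10 lists passed, and cyclic AMP and CREB targets had adjusted p = 0.000477 and 2.8e-05, with 3 and 6 up over the list alone, and adjusted p = 0.779 and 0.424 with an estimated correlation.

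In the fibroblast fraction Egr1, an early response transcription factor of growth signals, was lower with the drugs, and 3 of 22 cyclic AMP and CREB targets were higher. That list had a camera adjusted p = 0.00229, and adjusted p = 0.146 with an estimated correlation, and with a covariate for the epithelial share 1 gene passed in the whole comparison. Without the covariate, 20 of 20 called genes moved in the direction of the fold change between fractions, where 72.9% of all genes did. The same 20 had the same sign in the epithelial libraries, where 70.3% of all genes did. These changes are therefore not shown to be in fibroblasts. Averaged over CSE, Egr1 fell by 0.73 ± 0.06 (adjusted p = 0.000765, down in 6 of 6 pairs), from 479 CPM (SD 33.4, n = 3) in FibVeh to 294 (SD 16.9, n = 3) in FibTF, and from 470 (SD 25, n = 3) in FibCSE to 278 (SD 18.6, n = 3) in FibCSETF. Nr4a2 rose by 0.90 ± 0.11 (adjusted p = 0.0235), Areg by 0.67 ± 0.07 (adjusted p = 0.0094) and Cyp2b10 by 1.35 ± 0.14 (adjusted p = 0.0094). Further rises were Muc5b (2.00 ± 0.30, adjusted p = 0.0408) and Fam84a (0.81 ± 0.12, adjusted p = 0.0408). They also held the hyaluronan synthase gene Has2 (0.60 ± 0.09, adjusted p = 0.0456), the choline transporter gene Slc44a4 (0.60 ± 0.09, adjusted p = 0.0408) and Rhpn2 (0.55 ± 0.08, adjusted p = 0.0304). Falls were the matrix protease gene Mmp10 (-1.04 ± 0.14, adjusted p = 0.0268), Serpina3g (-0.80 ± 0.11, adjusted p = 0.0304), the matrix gene Islr (-0.71 ± 0.09, adjusted p = 0.0235) and the ceramide synthase gene Cers4 (-0.59 ± 0.09, adjusted p = 0.0408). Smaller falls were those of the collectin gene Colec12 (-0.56 ± 0.07, adjusted p = 0.0281), the glycosyltransferase gene B3galnt1 (-0.50 ± 0.07, adjusted p = 0.0304) and the transcription factor gene Tcf12 (-0.31 ± 0.04, adjusted p = 0.033). Each of them moved the same way in 6 of 6 pairs. Named after the values were seen, Dusp1, a phosphatase gene that shuts off kinases (0.54 ± 0.08, adjusted p = 0.04), and Pyy (2.16 ± 0.34, adjusted p = 0.0451) rose as well. The adhesion gene Vcam1 fell by 0.31 ± 0.05 (adjusted p = 0.0427).

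In this comparison 20 of 18287 genes passed, 11 up and 9 down, with 706 in DESeq2 and 464 with the block, 293 up and 171 down. The block added rises of Plet1, a progenitor surface gene (1.23 ± 0.14, adjusted p = 0.0137), Krt23 (1.18 ± 0.16, adjusted p = 0.0169) and Muc5ac (1.17 ± 0.21, adjusted p = 0.0308). Further additions were Anxa10 (1.45 ± 0.27, adjusted p = 0.0357), Nat8l (1.48 ± 0.26, adjusted p = 0.0284) and Tigit (1.22 ± 0.23, adjusted p = 0.0313). It added falls of the matrix proteases Mmp13 (-0.95 ± 0.18) and Mmp3 (-0.88 ± 0.17), both at adjusted p = 0.0321, S100a4 (-0.85 ± 0.10, adjusted p = 0.0137) and Olfml3 (-0.79 ± 0.10, adjusted p = 0.0154). Others were Amelx (-1.10 ± 0.23, adjusted p = 0.0407), Mrvi1 (-1.05 ± 0.20, adjusted p = 0.0321) and Fgf10 (-0.48 ± 0.10, adjusted p = 0.0418). The share of epithelial RNA was not measured apart from its genes. Epcam averaged 419 CPM (SD 132, n = 3) in FibVeh, 547 (SD 132, n = 3) in FibTF, 313 (SD 72.3, n = 3) in FibCSE and 492 (SD 114, n = 3) in FibCSETF. Without mouse 1 the count was 288, without mouse 2 it was 0 and without mouse 3 it was 1. Leaving out single libraries gave 4 without FibVeh replicate 1, 89 without FibCSE replicate 1 and 47 without FibCSETF replicate 1. It gave 3, 4, 3 and 5 without replicate 2, and 2, 3, 4 and 4 without replicate 3, of FibVeh, FibCSE, FibTF and FibCSETF in that order.

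Without CSE Egr1 alone passed for the drugs and was lower in this fraction (-0.71 ± 0.08, adjusted p = 0.0371, 0 of 3 pairs up). With the block its adjusted p was 0.0557, with the covariate for the other fraction its value was -0.66 (adjusted p = 0.111), and leaving out any of the 6 libraries gave 0 genes. Nr4a2 had 0.96 ± 0.16 and Islr -0.78 ± 0.13, both at an adjusted p of 0.506. The ribosomal protein gene Rps27 had -0.45 ± 0.08 and the zinc finger gene Zbed4 0.90 ± 0.16, both at 0.514. After CSE, Cyp2b10 rose by 1.83 ± 0.20 and Egr1 fell by 0.75 ± 0.08 (both adjusted p = 0.0174, in 3 of 3 pairs). With the covariate Egr1 had -0.68 there (adjusted p = 0.128). Areg had 0.80 ± 0.10 (adjusted p = 0.0519, and 0.0349 with the block), Tcf12 -0.42 ± 0.06 and Colec12 -0.69 ± 0.11 (both adjusted p = 0.141). With the block 6 genes passed, adding Muc1 (0.74 ± 0.09) and Dusp1 (0.64 ± 0.08), both at adjusted p = 0.0349. The count of 2 became 0 without mouse 2, FibCSE replicate 1 or 2 or FibCSETF replicate 2. It was 1 without mouse 3 or FibCSETF replicate 3, and 4 without FibCSETF replicate 1. DESeq2 called 20 genes without and 164 after CSE. Of 35 lists 7 passed camera without and 13 after CSE, and 0 with an estimated correlation.

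**Figure D2:**
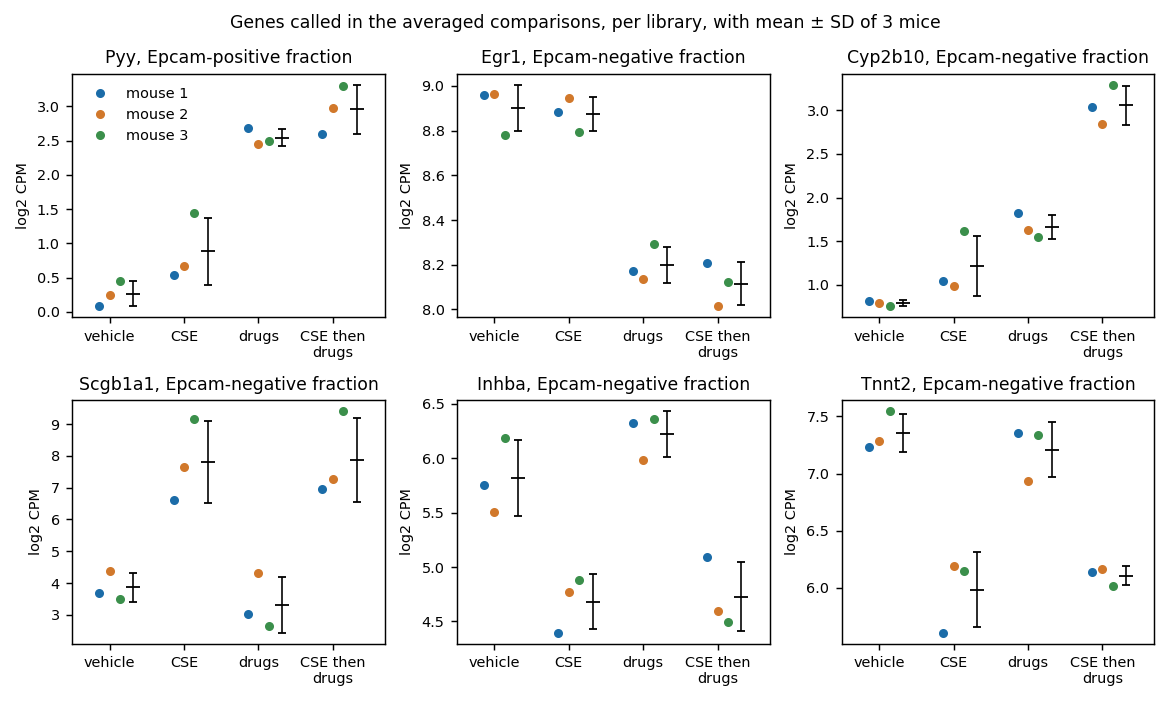
Log2 CPM by treatment of Pyy in the epithelial fraction and of Egr1, Cyp2b10, Scgb1a1, Inhba and Tnnt2 in the fibroblast fraction. Points are libraries coloured by mouse, with mean and SD.

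Of the lists, 13 of 35 passed camera for the averaged drug effect in the fibroblast fraction. Cyclic AMP and CREB targets had a median of 0.15 over 22 genes, 3 up and 0 down, with 5 up and 1 down over the list alone (adjusted p = 0.00229, and adjusted p = 0.146 with an estimated correlation). Transitional cell genes, marks of cells on the way to alveolar type 1, had 0.46 over 15, with 1 up (Areg) and 8 up over the list alone. Itgb6 had 0.79 ± 0.18 and Krt7 0.50 ± 0.12 (camera adjusted p = 5.26e-07, and adjusted p = 0.337 with an estimated correlation). Goblet cell genes had 0.57 over 11, with 1 up (Muc5b), 5 over the list alone, and Muc4 at 0.59 ± 0.12 (adjusted p = 0.00155, and adjusted p = 0.183 with an estimated correlation). Epithelial identity had 0.49 over 17 with 0 called and 10 up over the list alone, with Cldn3 at 0.65 ± 0.14 (adjusted p = 5.26e-07, and adjusted p = 0.397 with an estimated correlation). Fibroblast matrix had -0.37 over 20 with 0 called, 1 down over the list alone and Col6a3 at -0.48 ± 0.11 (adjusted p = 0.0023, and adjusted p = 0.397 with an estimated correlation). Fibroblast identity had -0.34 over 10 with 0 called, 1 up and 5 down over the list alone, and Prrx1 at -0.47 ± 0.12 (adjusted p = 0.00639, and adjusted p = 0.523 with an estimated correlation).

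The rest of the lists for this effect had few or no called members. The cell cycle list had -0.42 over 20 with Tyms at -0.44 ± 0.15 (adjusted p = 0.0023, and adjusted p = 0.741 with an estimated correlation). FGF and ERK targets had -0.11 over 13, with 1 down (adjusted p = 0.0398, 0.0661 with the block, and adjusted p = 0.337 with an estimated correlation). Mesothelial genes had 0.48 over 8, 4 up over the list alone, with Msln at 0.49 ± 0.09 (adjusted p = 0.000937, and adjusted p = 0.145 with an estimated correlation). Alveolar type 1 genes had 0.31 over 16 (adjusted p = 0.0068), NRF2 targets 0.12 over 20 (adjusted p = 0.00639), interferon 0.30 over 18 (adjusted p = 0.00229) and cholesterol 0.17 over 18 (adjusted p = 0.00135). These had adjusted p = 0.55, 0.359, 0.55 and 0.607 with an estimated correlation. Fry called the goblet (adjusted p = 0.0117), cyclic AMP (0.00488), mesothelial (0.00488) and FGF (0.0117) lists. The fixed genes Pde4a (-0.16 ± 0.09, adjusted p = 0.447), Pde4b (adjusted p = 0.277) and Pde4d (adjusted p = 0.537) did not pass.

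The test of whether the drug effect differed after CSE called 0 genes in each fraction. The interaction passed for 0 genes in the epithelial fraction, with 207 at an unadjusted p under 0.05, 1 in DESeq2, and 1 without EpiCSETF replicate 3. The smallest p belonged to Amot, a gene of the Hippo pathway (-0.37 ± 0.10), Lrch4 (1.06 ± 0.31), Nol12 (-0.32 ± 0.10) and the transcription factor gene Foxp1 (1.24 ± 0.37), each at an adjusted p of 1. The fibroblast interaction passed for 0 genes, with 362 at an unadjusted p under 0.05, 0 in DESeq2, and 1 without FibCSETF replicate 1 or replicate 3. Uchl3, which removes ubiquitin (0.40 ± 0.09), Rps27 (0.40 ± 0.11) and the respiratory chain gene Ndufa4 (0.28 ± 0.08) led there. Cyp2b10, named after its values were seen, had 0.96 ± 0.29 (adjusted p = 1), from 1.73 CPM in FibVeh to 3.18 in FibTF, and from 2.37 in FibCSE to 8.39 in FibCSETF. With the block the predicted gene Gm20716 passed, which had 0 CPM in FibVeh and FibCSETF and a mean of 30.2 in FibCSE and 42.8 in FibTF, so no fold is given. In the epithelial fraction the interferon list (median 0.25, adjusted p = 0.00456) and the dissociation list (0.18, adjusted p = 0.00722) passed camera, both at adjusted p = 0.832 with an estimated correlation, and 0 lists passed in the fibroblast fraction.

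Across all genes, the drug effects without and after CSE had a Pearson r of 0.28 and a Spearman r of 0.32 in the epithelial and 0.26 and 0.42 in the fibroblast fraction. Of genes with an unadjusted p under 0.05, 61 had positive folds in both arms of the epithelial fraction, out of 213 without and 394 after CSE, where 4.65 were expected. For the fibroblast libraries it was 223, out of 549 and 973, where 29.2 were expected. The expected counts take both arms as independent. Both came from the same fit, with a shared estimate of the spread per gene, and from the same mice. The excess can therefore not be read as agreement of the drug effect alone. The test of whether the drug effect differed between the fractions called 0 genes, with 499 at an unadjusted p under 0.05, 1 in DESeq2, and 1 without mouse 3 or EpiCSETF replicate 3. Egr1 had -0.33 ± 0.11 (adjusted p = 0.718) in the epithelial against -0.73 in the fibroblast fraction, while Nr4a2 had 0.76 against 0.90 and Areg 0.47 against 0.67. The smallest p for the difference belonged to the polarity gene Llgl2 (-0.29 ± 0.08), Tns4 (-0.52 ± 0.16) and Dok7 (-0.58 ± 0.18), each at an adjusted p of 1. Of the lists 7 passed camera for it, led by epithelial identity (median -0.32, adjusted p = 1.02e-05) and transitional genes (-0.32, adjusted p = 0.000237), both at adjusted p = 0.475 with an estimated correlation.

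In the epithelial fraction a single gene passed for earlier CSE, Camk2n1, an inhibitor of a calcium-dependent kinase. Other splits of the libraries called as many genes in 4 of 100 cases, the real one included, with 1 as the highest other. Averaged over drugs, Camk2n1 fell by 0.63 ± 0.07 (adjusted p = 0.0345, down in 6 of 6 pairs). Values of the next genes were -0.74 ± 0.10 for the troponin gene Tnnt2 (adjusted p = 0.0538), -1.02 ± 0.14 for the receptor gene Tnfrsf26 (adjusted p = 0.0589), -0.56 ± 0.08 for the Wnt pathway receptor gene Lgr6 (adjusted p = 0.0619) and -0.39 ± 0.06 for the growth factor gene Vegfa (adjusted p = 0.0911). DESeq2 called 189 genes, and 1512 had an unadjusted p under 0.05. The count was 17 without EpiVeh replicate 2, 3 without EpiCSE replicate 1, and 2 without EpiTF replicate 1 or EpiCSE replicate 2. It was 0 without any mouse, EpiVeh replicate 1 or 3, EpiCSE replicate 3, EpiTF replicate 2 or 3, or EpiCSETF replicate 1.

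With the block 181 genes passed, 78 up and 103 down. Labels exchanged within mice called as many in 2 of 32 cases, the real one included, and up to 218 genes, so these calls are given as values. Positive values were those of the sulfotransferase gene Sult1d1 (3.83 ± 0.42, adjusted p = 0.00795), the transporter gene Slc16a12 (1.05 ± 0.11, adjusted p = 0.00373), the growth factor gene Ptn (0.87 ± 0.10, adjusted p = 0.00795) and Dapl1 (0.89 ± 0.14, adjusted p = 0.0278). Others were Cyfip2 (0.90 ± 0.16, adjusted p = 0.0391), Car12 (1.13 ± 0.20, adjusted p = 0.0422), Bmp3 (1.11 ± 0.20, adjusted p = 0.0451) and Ager (0.98 ± 0.19, adjusted p = 0.0492). Negative values were those of the oxidase gene Duox2 (-1.48 ± 0.17, adjusted p = 0.00795), the iron-binding gene Lcn2 (-1.19 ± 0.20, adjusted p = 0.047) and complement factor B, Cfb (-1.06 ± 0.15, adjusted p = 0.0244). Hsd17b2 (-1.54 ± 0.25, adjusted p = 0.0385), Trim15 (-1.22 ± 0.17, adjusted p = 0.0303), Tnfrsf26 (-1.03 ± 0.12, adjusted p = 0.00795), Prss12 (-1.01 ± 0.18, adjusted p = 0.0499) and Bcl2l15 (-0.99 ± 0.09, adjusted p = 0.00312) were negative too. Without drugs, CSE against vehicle passed for 0 genes, with 667 at an unadjusted p under 0.05, 16 in DESeq2 and 0 with the block. Camk2n1 led with -0.79 ± 0.10 (adjusted p = 0.118), before Lgr6 (-0.61 ± 0.11) and the interferon genes Oasl2 (-0.83 ± 0.15), Xaf1 (-0.53 ± 0.10) and Rtp4 (-0.74 ± 0.15), each at 0.833 and lower in 3 of 3 pairs.

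By list, 9 of 36 passed camera for the averaged CSE effect in the epithelial fraction, with 0 members called. Medians were positive for alveolar type 2 genes (0.72 over 18, 6 up over the list alone, adjusted p = 1.91e-08) and club cell genes (0.56 over 15, 6 up, adjusted p = 1.43e-06). They were also positive for basal genes with Trp63 at 0.48 ± 0.08 (0.43 over 10, 5 up, adjusted p = 6.89e-05), NOTCH genes with Dll1 at 0.65 ± 0.13 (0.34 over 10, 5 up, adjusted p = 5.62e-05) and FGF and ERK targets (0.14, adjusted p = 0.0333). Negative medians were those of interferon genes with Irf7 at -0.50 ± 0.11 (-0.29 over 18, 6 down over the list alone, adjusted p = 1.91e-08) and goblet genes with Muc16 at -0.64 ± 0.16 (-0.60 over 11, 4 down, adjusted p = 0.000243). Others were those of transitional genes (-0.16 over 15, 3 down, adjusted p = 4.43e-06) and retinoic acid genes (-0.24 over 9, 3 down, adjusted p = 1.75e-05). With an estimated correlation 0 passed, at adjusted p = 0.0609 with an estimated correlation for NOTCH, 0.0879 for retinoic acid, 0.199 for goblet and 0.218 for interferon. It was 0.279 for basal, 0.317 for alveolar type 2 and 0.336 for club, transitional and FGF. Fry called NOTCH (adjusted p = 0.00401) and retinoic acid (adjusted p = 0.0172). Values for single club and alveolar genes were 3.03 ± 0.57 for Scgb1a1 (adjusted p = 0.134) and 1.81 ± 0.48 for Sftpc (adjusted p = 0.319). Without drugs 11 lists passed, led by interferon (-0.49, 8 down over the list alone, adjusted p = 1.68e-11, and adjusted p = 0.133 with an estimated correlation).

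In the fibroblast fraction earlier CSE raised 4 of 15 club cell genes and 8 of 18 alveolar type 2 genes. Both lists passed camera, with adjusted p = 0.285 with an estimated correlation. These are genes of epithelial cells, whose RNA this fraction kept, so the rises are not shown to be in fibroblasts. The epithelial identity list had mean log2 CPM of 6.36 in FibVeh, 6.54 in FibCSE, 6.70 in FibTF and 7.06 in FibCSETF. Epcam was lower after CSE, with 419, 313, 547 and 492 CPM in the same order. It was also lower after CSE in the epithelial fraction itself, at 1333 CPM in EpiVeh and 1045 in EpiCSE, and 1467 in EpiTF and 1169 in EpiCSETF. Its fall therefore does not show which way the share went. Cdh1, another gene of the list, averaged 432, 455, 628 and 680 CPM in the 4 fibroblast groups in the order above. Averaged over drugs, the club cell genes Scgb1a1 (4.54 ± 0.62, adjusted p = 0.00663) and Scgb3a2 (3.13 ± 0.53, adjusted p = 0.0145) rose. So did Sftpc (2.59 ± 0.55, adjusted p = 0.0316, and 0.0827 with the block), the lung chemokine gene Cxcl15 (2.42 ± 0.38, adjusted p = 0.011) and the surfactant gene Sftpb (2.18 ± 0.37, adjusted p = 0.0141). Scgb1a1 averaged 15 CPM (SD 5.02, n = 3) in FibVeh, 11.4 (SD 7.39, n = 3) in FibTF, 292 (SD 251, n = 3) in FibCSE and 319 (SD 310, n = 3) in FibCSETF. Other rises were the protease inhibitor gene Spink5 (3.65 ± 0.67, adjusted p = 0.0187), the esterase gene Pon1 (3.51 ± 0.54, adjusted p = 0.0101), the vesicle gene Synpr (2.70 ± 0.46, adjusted p = 0.0141) and the integrin gene Itga9 (2.22 ± 0.47, adjusted p = 0.0306). Fixed genes that rose were Ager (1.98 ± 0.36, adjusted p = 0.0175) and Cyp1b1 (0.50 ± 0.12, adjusted p = 0.0441). With the block the largest rises also held Bmp3 (2.15 ± 0.31) and the glutathione transferase gene Gstt1 (2.08 ± 0.20, adjusted p = 0.00133). The largest falls with it held Ppbp (-1.81 ± 0.33, adjusted p = 0.0201) and Hsd17b2 (-1.35 ± 0.28, adjusted p = 0.0188).

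The falls after CSE included Inhba and Lrrc32, while the list of TGF-beta and myofibroblast genes had 0 up and 1 down of 16 (camera adjusted p = 0.301). The mean log2 CPM of that list split by mouse. Without drugs it was 5.35 in FibVeh and 6.64 in FibCSE for mouse 1, 5.44 and 5.01 for mouse 2, and 5.52 and 5.07 for mouse 3. With drugs it was 5.24 and 6.06, 5.31 and 5.08, and 5.27 and 4.97. Inhba, which encodes a subunit of activin, fell by 1.31 ± 0.15 (adjusted p = 0.00337), and Lrrc32, which holds latent TGF-beta at the cell surface, by 1.13 ± 0.17 (adjusted p = 0.00846). Tnnt2 (-1.23 ± 0.11, adjusted p = 0.00192), the retinol receptor gene Stra6 (-1.24 ± 0.17, adjusted p = 0.0066) and the vesicle gene Syt7 (-1.27 ± 0.14, adjusted p = 0.00341) fell too. Further falls were the envelope gene Lce1g (-1.32 ± 0.16, adjusted p = 0.00382), Bcl2l15 (-1.37 ± 0.27, adjusted p = 0.0224) and the centromere gene Cenpm (-1.26 ± 0.28, adjusted p = 0.0394). Each of these falls and of the 8 largest rises held in 6 of 6 pairs. Of the fixed genes Fgf7 (-0.42 ± 0.09, adjusted p = 0.0263) and Hmox1 (-0.40 ± 0.07, adjusted p = 0.0127) fell. Pde4b had 0.58 ± 0.21 (adjusted p = 0.139). Acta2, fibroblast CSE effect averaged over drugs, had 2.42 ± 1.00 (adjusted p = 0.197), and without mouse 1 its direction turned, to -0.79 (adjusted p = 0.0254). In all 733 of 18287 genes passed, 335 up and 398 down, with 1762 in DESeq2 and 1589 with the block. The count was 758 without mouse 1, 95 without mouse 2 and 0 without mouse 3. Leaving out FibVeh replicate 1 gave 236, FibCSE replicate 1 1117, FibTF replicate 1 188, FibCSE replicate 2 427 and FibCSETF replicate 2 340. Leaving out replicate 3 gave 180, 311, 146 and 239 for FibVeh, FibCSE, FibTF and FibCSETF.

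By list, 13 of 35 passed camera here. Alveolar type 2 genes had a median of 1.08 over 18, 8 up and 0 down, 12 up over the list alone, with Scd1 at 1.41 ± 0.27 (adjusted p = 4.47e-07, and adjusted p = 0.285 with an estimated correlation). Club cell genes had 1.28 over 15, 4 up, 11 over the list alone, with Hp at 2.16 ± 0.39 (adjusted p = 1.36e-07, and adjusted p = 0.285 with an estimated correlation). FGF and ERK targets had 0.19 over 13, 5 up and 1 down, with Dusp6 at 0.36 ± 0.05, Etv1 at 0.56 ± 0.09 and Spred1 at 0.31 ± 0.05 (adjusted p = 0.0201, and adjusted p = 0.285 with an estimated correlation). Retinoic acid genes had -0.23 over 9, 3 down, with Cyp26b1 at -0.84 ± 0.17 (adjusted p = 0.00041, and adjusted p = 0.107 with an estimated correlation). The unfolded protein response had -0.19 over 15, 1 up and 2 down, 1 up and 9 down over the list alone, with Asns at -0.55 ± 0.07 and Chac1 at -0.60 ± 0.10 (adjusted p = 0.000708, and adjusted p = 0.285 with an estimated correlation). Basal genes had 0.63 over 10, 2 up, with Trp63 at 0.85 ± 0.20 and Aqp3 at 0.65 ± 0.12 (adjusted p = 0.00586, and adjusted p = 0.319 with an estimated correlation).

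Cyclic AMP and CREB targets had 0.21 over 22, 4 up and 1 down, with Fos at 0.76 ± 0.13, Nr4a2 at 0.53 ± 0.11 and Areg at -0.38 ± 0.07 after CSE (adjusted p = 0.0344, 0.0739 with the block, and adjusted p = 0.285 with an estimated correlation). The dissociation response had 0.21 over 14, 2 up, with Zfp36 at 0.43 ± 0.08 (adjusted p = 0.00194), and antigen presentation 0.28 over 13, 1 up, with H2-K1 at 0.36 ± 0.08 (adjusted p = 0.00976). Both had adjusted p = 0.285 with an estimated correlation. Ciliated (0.43 over 17, adjusted p = 0.0201), cholesterol (-0.18 over 18, adjusted p = 0.00256) and mitochondrial genes (0.23 over 9, adjusted p = 0.00776) had 0 called and adjusted p = 0.554 with an estimated correlation. The p53 targets (-0.13 over 15, adjusted p = 0.00194) had 0 called and adjusted p = 0.319 with an estimated correlation. NOTCH genes had 0.45 over 10, 2 up, with Notch1 at 0.56 ± 0.07 and Dll1 at 1.06 ± 0.25 (adjusted p = 0.0526, 0.043 with the block, and adjusted p = 0.387 with the block and an estimated correlation). Fry called 12 lists, from retinoic acid (adjusted p = 0.00211) and FGF and ERK (0.00454) through club, cyclic AMP and dissociation (each 0.0161), alveolar type 2 (0.0188), unfolded protein (0.022), antigen presentation and NOTCH (each 0.0234) to basal (0.0333), support factors (0.0422) and p53 (0.0481).

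Without drugs, CSE against vehicle changed 19 genes in the fibroblast fraction, 2 up and 17 down. The count was 0 with only the compared groups in the fit and 197 with the covariate for the other fraction. The transcription factor gene Cebpd (0.72 ± 0.11) and the receptor gene Notch1 (0.68 ± 0.11) rose, both at adjusted p = 0.0476 and in 3 of 3 pairs. Falls in 3 of 3 pairs were Tnnt2 (-1.36 ± 0.16, adjusted p = 0.0251), the matrix gene Smoc2 (-1.29 ± 0.18, adjusted p = 0.0379), the potassium channel gene Kcnn4 (-1.13 ± 0.16, adjusted p = 0.0379) and Has2 (-0.98 ± 0.13, adjusted p = 0.0379). So were Mmp24 (-1.23 ± 0.18, adjusted p = 0.0427), Dynap (-0.95 ± 0.14, adjusted p = 0.0387), and Lce1g (-1.47 ± 0.23) and Syt7 (-1.31 ± 0.20), both at adjusted p = 0.0476. With the block 124 genes passed, 47 up and 77 down. It added rises of Gstt1 (1.85 ± 0.27, adjusted p = 0.0193), Ly6c1 (1.39 ± 0.22, adjusted p = 0.0251), the Wnt inhibitor gene Apcdd1 (1.34 ± 0.22, adjusted p = 0.0309) and the selenium carrier gene Sepp1 (1.33 ± 0.24, adjusted p = 0.0481). It also added the receptor gene Fgfr2 (1.20 ± 0.20, adjusted p = 0.0392), Rragd (1.17 ± 0.16, adjusted p = 0.0146), Bmp4 (1.16 ± 0.20, adjusted p = 0.0431) and Ccdc3 (1.15 ± 0.21, adjusted p = 0.0468). Falls it added were those of Cenpm (-1.28 ± 0.16, adjusted p = 0.0123), Bcl2l15 (-1.41 ± 0.21, adjusted p = 0.0207) and Stra6 (-1.30 ± 0.22, adjusted p = 0.0434). DESeq2 called 599. The count of 19 was 7 without mouse 1 and 0 without mouse 2 or 3. It was 11 without FibCSE replicate 1, 8 without FibVeh replicate 2, and 0 without FibVeh replicate 1 or 3 or FibCSE replicate 2 or 3. Of the lists 11 of 35 passed, led by alveolar type 2 (1.40, 11 up over the list alone, adjusted p = 5e-06) and club (1.37, 5 up, adjusted p = 2.84e-05), both at adjusted p = 0.422 with an estimated correlation.

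Although 733 genes passed in the fibroblast and 1 in the epithelial fraction, the CSE effect differed between fractions for 0 genes, a comparison added after these counts were seen. It had 1652 genes at an unadjusted p under 0.05, 78 in DESeq2, and with the block the protease gene Prss23 (0.65 ± 0.08, adjusted p = 0.00866). Prss23 fell by 0.89 ± 0.08 in the fibroblast fraction and had -0.25 ± 0.13 (adjusted p = 0.648) in the epithelial. The smallest p otherwise belonged to the anchoring collagen gene Col7a1 (0.96 ± 0.16, adjusted p = 0.146), and to Efna3 (0.94 ± 0.18), the hyaluronan-degrading gene Cemip (1.40 ± 0.27) and Rab20 (-0.60 ± 0.12), each at 0.188. Leaving out mouse 3, FibCSETF replicate 1, FibCSE replicate 2, FibTF replicate 2 or EpiCSETF replicate 3 gave 1 gene each. Of the lists 9 passed camera. Interferon genes had a median difference of -0.42 (2 down over the list alone, adjusted p = 3.39e-06) and antigen presentation -0.47 (adjusted p = 0.000483), both at adjusted p = 0.651 with an estimated correlation.

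**Figure D3:**
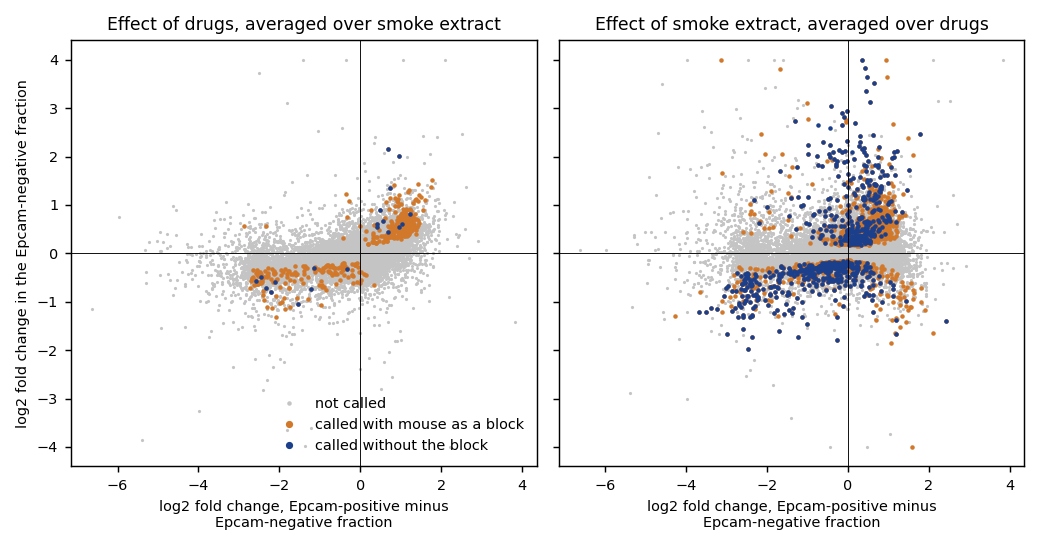
Log2 fold change in the fibroblast fraction of the drugs and of CSE against the log2 fold change between fractions. Grey genes were not called, orange were called with mouse as a block, and blue without it; 17 points beyond 4 are drawn at 4.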

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

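Other size factors left each count within 1.5-fold. Without a filter the epithelial counts were 1 for CSE without drugs, 1 and 1 for drugs without and after CSE, 2 for the averaged drug effect and 11 for the averaged CSE effect. The fibroblast count was 47 for CSE without drugs, 30 for the averaged drug effect and 517 for the averaged CSE effect.

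DESeq2 called 16, 9, 15, 69 and 189 genes in the epithelial fraction in the order CSE, drugs without CSE, drugs after CSE, averaged drugs and averaged CSE, and 1 for the interaction. Among fibroblast genes it called 599, 20, 164, 706 and 1762 in the same order. It called 1 gene for the drug difference and 78 for the CSE difference between fractions.

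With mouse as a block the epithelial counts were 1 and 1 for drugs without and after CSE, 37 for averaged drugs and 181 for averaged CSE. The fibroblast counts were 124 for CSE, 6 for drugs after CSE, 464, 1589 and, for the interaction, 1, and the CSE difference between fractions had 1. Of the named genes only Egr1 for drugs without CSE and Sftpc for averaged CSE lost their call with the block, and the calls it added are given beside each result.

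With the covariate for the other fraction the epithelial counts were 1 for drugs after CSE, 5 for averaged drugs and 16 for averaged CSE. The fibroblast counts with it were 197 for CSE, 0 and 0 for drugs without and after CSE, 1 for averaged drugs and 737 for averaged CSE, of which 414 were in the 733. Block and covariate together, added after the data were seen, gave 2, 5, 10 and 47 in the epithelial fraction for drugs without CSE, drugs after CSE, averaged drugs and averaged CSE. For the fibroblast libraries they gave 102 for CSE, 0 for drugs after CSE, 0 for averaged drugs, 179 for averaged CSE and 1 for the interaction.

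With only the compared groups in the fit, the epithelial counts were 1 for CSE and 2 for drugs without CSE, and the 3 fibroblast counts were 0. The block without FibCSE replicate 1, also added, gave 187 for CSE, 1 for drugs after CSE, 993 for averaged drugs and 1880 for averaged CSE. With the covariate too, averaged drugs had 0 and averaged CSE 592. Leaving out NewGene loci, also added, gave 743 for averaged CSE and 20 for averaged drugs.

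Leaving out a library or mouse gave, in the epithelial fraction, 0 to 1 for drugs after CSE, 0 to 4 for averaged drugs, 0 to 17 for averaged CSE and 0 to 1 for the interaction. For fibroblast libraries it gave 0 to 11 for CSE, 0 for drugs without CSE, 0 to 4 for drugs after CSE, 0 to 288 for averaged drugs, 0 to 1117 for averaged CSE and 0 to 1 for the interaction. It gave 11103 to 13500 for the fractions and 0 to 1 for each difference between fractions.

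Of 531 list tests 132 passed camera, 0 with an estimated correlation, 160 with the block, 50 by fry and 64 by fry with the block. Since 0 passed with an estimated correlation even between the fractions, that setting does not decide whether a list moved. The passes at the preset correlation are not settled by it either. Of 197 named gene values none that was called changed sign, and calls were lost for 24 with the covariate, 2 with the block, 8 without a filter and 24, 48 and 53 without mouse 1, 2 and 3. Values that were not called did so for 27 with the covariate, 3 with the block and 9, 5 and 7 without mouse 1, 2 and 3. With at least 10 CPM the drug effects without and after CSE had a Pearson r of 0.28 and a Spearman r of 0.40 in the epithelial fraction, and 0.18 and 0.57 in the fibroblast fraction.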

Other observations

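The fibroblasts in the sequenced cultures were fresh at day 14, yet some genes linked to activin and TGF-beta were lower in their fraction after earlier CSE, while the list of TGF-beta and myofibroblast genes did not pass, with 0 up and 1 down of 16 (camera adjusted p = 0.301). FibCSE and FibCSETF replicate 1 had list means of 6.64 and 6.06, and the other libraries with CSE 4.97 to 5.08. Inhba had -1.31 ± 0.15 and Lrrc32 -1.13 ± 0.17. Named after the values were seen, the feedback genes Smad7 (-0.55 ± 0.05, adjusted p = 0.00192) and Pmepa1 (adjusted p = 0.00237) and the activin-binding gene Fstl3 (-0.64 ± 0.08, adjusted p = 0.00416) fell with them. Ctgf (0.40 ± 0.23, adjusted p = 0.351) and Skil (adjusted p = 0.248) did not pass. Of the 1314 genes at least 4-fold higher in the fibroblast fraction 75 fell and 2 rose after CSE, and with the block 111 fell and 14 rose. Those that fell included Smoc2 (-1.07 ± 0.13), Cd93 (-1.03 ± 0.19) and the growth factor Fgf2 (-1.03 ± 0.17). A larger share of epithelial RNA would lower such genes too, and that share was not measured apart from its genes. FibVeh and FibTF had epithelium without CSE, and no library of fibroblasts grown alone was there to tell a signal of the epithelial cells from other causes.

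The tests of genes near the same level in both fractions, of genes highest in either fraction and of the size of the fold, the 4 tests of splits with the mouse block, the fry test, the fit with block and covariate and the CSE difference between fractions were chosen only after the results were seen. In the tests of genes near the same level, which took genes of at least 10 CPM within 0.5 (log2) of the same level, the bar was raised from the median alone to the median plus 2 SD, after all 587 such genes called for CSE had passed the lower bar. The first pattern is the averaged drug effect in the fibroblast fraction with the block, in which 452 of 464 called genes, or 97.4%, moved in the direction of the fold change between fractions, where 72.9% of all genes did, which is consistent with a larger share of epithelial RNA after the drugs. Against that direction moved 2 of 224 called genes highest in either fraction, and of 54 called genes near the same level 0 had a fold beyond the bar (1.04), neither of which excludes anything. The covariate ended each call made with the block, as the median fold of the 464 genes fell from 0.50 (median SE 0.09) to 0.29 (median SE 0.12), with the same sign in 100%, so the share may be a part and is not shown to be the whole. An epithelial response carried over was not excluded. Of the 463 genes compared, 99.6% had the same sign in the epithelial libraries, and 30.2% had a larger fold than there by over 2 SE of the difference. These genes were chosen by their fold in the fibroblast fraction, which favours larger folds in it. The test of the drug difference between fractions called 0 genes, so the size of the fold does not decide. A response of the fibroblasts stays open and was not tested apart from these.

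For the second pattern, the averaged CSE effect in the fibroblast fraction with the block, 78.2% of the 1589 called genes moved in the direction of the fold change between fractions, where 63.9% of all genes did. A different share of epithelial RNA could not be the whole cause, since 59 of 229 called genes highest in either fraction moved against that direction. Of 587 called genes near the same level, 26 had a fold beyond the bar (0.96). These were 1.64% of the called genes, below the share set for that test. They included club and alveolar genes such as Scgb1a1, Sftpb and Ager, so they do not decide. With block and covariate 179 genes passed, and the median fold of the 1589 went from 0.46 (median SE 0.09) to 0.38 (median SE 0.10), so a part of the pattern may come from the share. An epithelial response carried over was not excluded. Of the 1565 genes compared, 85% had the same sign in the epithelial libraries, and 50.9% had a larger fold than there by over 2 SE of the difference. These genes too were chosen by their fold in the fibroblast fraction. The test of the CSE difference between fractions called 0 genes, and 1 with the block. A response carried over and a response of the fibroblasts to the exposed epithelium both stay open.

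The third pattern is FibCSE replicate 1, which held Col1a1 at 2207 CPM and Acta2 at 304.5, where Acta2 was between 5.343 and 18.32 in the fibroblast libraries other than FibCSETF replicate 1 (106.2). Its deviation correlated at -0.04 with the fold change between fractions, so less epithelial RNA does not account for that deviation across all genes. A lower share as a part of it is not excluded. The epithelial identity list had mean log2 CPM of 6.21 in this library, against 6.55 and 6.87 in FibCSE replicates 2 and 3. Fibroblast identity had 6.98, against 6.1 and 6.19. Epcam, at 281.7 CPM, lay between their 261.3 and 395.5. A difference of mouse 1 might be an explanation. The library's deviation correlated at 0.68 with that of mouse 1 in FibCSETF, though at 0.23 and 0.22 in FibVeh and FibTF, so that it cannot be told. With the block and without this library the averaged CSE count was 1880 and the averaged drug count 993.

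Splits of the same libraries into other groups showed how many genes the fits called when labels were exchanged, the real grouping counted among them. Among fibroblast libraries 1 of 100 splits called as many as the real 733 for the averaged CSE effect, with 234 as the highest other, and 1 of 100 as many as 20 for the averaged drug effect, with 1 as the highest other. For CSE without drugs it was 1 of 10 (highest other 0), for drugs without CSE 2 of 10 (highest other 1), and for drugs after CSE 1 of 10 (highest other 1), where 10 splits cannot reach 0.05. The comparison of fractions had 1 of 100, with 172 as the highest other. In the epithelial fraction 4 of 100 splits called as many as the real 1 for the averaged CSE effect, with 1 as the highest other, and 5 of 100 for the averaged drug effect, with 1913 as the highest other. The split with 1913 placed only 2 of the mouse pairs across its arms, so it also set mice against each other. The 3 pairwise comparisons of the epithelial fraction had 10 of 10, which 0 real calls always give, with 0, 0 and 1 as the highest other.

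For the interactions, and for the differences of the drug and CSE effects between fractions, all 100 splits called as many as the real 0. Any split reaches a count of 0, so this tests nothing. The highest others were 448 in the epithelial interaction, 79 for the drug and 428 for the CSE difference, which may reflect differences between mice and treatments that the exchanged labels pick up. The highest other in the fibroblast interaction was 20, the count of the averaged drug effect. Exchanging all drug labels within a single CSE level turns the interaction into that effect. With the mouse block and labels exchanged within mice, 1 of 32 splits reached the real count of 37 for the epithelial drug effect (highest other 0), 1 of 32 reached 464 for the fibroblast drug effect (highest other 1) and 1 of 32 reached 1589 for the fibroblast CSE effect (highest other 1). The epithelial CSE effect had 2 of 32, with 218 as the highest other against 181, so the calls made there with the block are not set apart from exchanged labels.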
